A study of Mus musculus with 16 samples.

How the data were processed

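Gene expression was measured in mouse embryonic fibroblasts (MEF) of 2 genotypes, wild-type and CHOP knockout, with 2 treatments, untreated or exposed to the proteasome inhibitor MG132 at 1 µM for 8 hours. Each of the 4 groups held 4 arrays, 16 in all, and the labels give a separate culture plate for each. The labels do not say whether the plates came from separate embryos or cell isolations, so the p-values measure the spread between these plates only. The labels of the untreated groups differ among themselves: the treatment field and titles give no treatment, whereas the sample descriptions name DMSO, the solvent, as a vehicle control. The groups are called untreated here and serve as the control in either case. If they received no DMSO, the MG132 contrasts also include any effect of the solvent.

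Per the labels, total RNA was labelled with biotin by a 3' in vitro transcription kit, hybridised to an Affymetrix mouse 3' expression array and summarised by the authors with MAS5, whose version and settings are not given in the sources used here. The deposited values are linear MAS5 signal intensities, 1 per probe set and array, with no log transformation and no detection calls. In each of the 16 columns the mean after trimming 2% of the values at each end was 1000, so the authors had scaled each array to a common trimmed mean. Columns were read as deposited, and replicates were not pooled.

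The table held 45101 probe sets, of which 64 were array controls, 9160 named no gene, 932 named several genes and 34945 named 1 gene. Gene names came from the probe table of the series. 34741 of the single-gene probe sets matched the gene reference by gene identifier, and 0 symbols changed in that match. No coordinates were used except gene order along chromosomes, which came from the same reference.

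Signals were taken as log2(signal + 16), with no further normalisation between arrays. Each gene was represented by its single-gene probe set with the highest mean over all arrays, and it was tested when that probe set lay above the median of its array on at least 4 of the 16 arrays, which left 11457 genes. Linear models were fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 16 arrays (12 residual degrees of freedom, 7.672 prior degrees of freedom) and an empirical Bayes variance with a mean-variance trend. 5 contrasts were tested, two-sided, with Benjamini-Hochberg (BH) adjustment over all genes and a threshold of 0.05. These were MG132 against untreated in each genotype, the difference between both responses (the interaction, knockout minus wild-type, so that a positive value means a higher response in the knockout), and knockout against wild-type at each treatment. Unless stated otherwise, a fold change is given on the log2 scale with its standard error (SE), and a signal as mean ± SD, each from 4 arrays per group. Adding 16 units to every signal limits fold changes of genes with signals near that value. "Rose", "fell", "higher" and "lower" mean past the BH threshold.

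32 gene lists were fixed before the data were examined. They cover targets of the integrated stress response (ISR) and ATF4, aminoacyl-tRNA synthetases, ER chaperones and ER-associated degradation (ERAD), heat shock proteins and cytosolic chaperones, 26S proteasome subunits, the immunoproteasome and antigen processing, the ubiquitin and p97 pathway, autophagy and p62, NRF2 antioxidant genes, apoptosis regulators, p53 targets, AP-1 and immediate early genes, NF-kB and cytokine genes, interferon response genes, mitotic genes, DNA replication genes, cholesterol synthesis and uptake, extracellular matrix, contractile and serum response genes, fibroblast identity, Hox genes, cytosolic ribosomal proteins, oxidative phosphorylation, sex-linked transcripts, and markers of macrophages and leukocytes, epithelium, endothelium, skeletal muscle, fat cells, cartilage and bone, neural cells, and placenta and red blood cells. Of 671 list entries, 67 had no probe set naming that gene alone. The 30 lists with at least 3 tested members were tested with limma camera (preset correlation between genes of 0.01), which compares a list with all other tested genes, with BH adjustment over the lists within a contrast. Members past the threshold were counted over all tested genes and, separately, adjusted over the list alone.

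Genes were named by a rule fixed before the data were examined. For each contrast these were the 10 largest changes in each direction among genes past the threshold whose 4 values in one group all lay above the 4 of the other (for the interaction, without the condition on overlap). Ddit3, Atf5 and, for each list described, up to 4 members with the smallest adjusted p were added, with any member that the definition of a list names and that did not pass, and unnamed clones were skipped. Any gene named outside this rule is marked as chosen after its values were seen. Array quality was compared with exact permutation tests (two-sided, BH over 24 comparisons), using the ratio of 3' to 5' control probe sets of Gapdh and Actb, the 10th, 50th and 75th percentiles of the signals and the hybridisation controls.

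The alternatives fixed in advance were pseudocounts of 1 and 64, no filter on low values or a filter at the 60th percentile, quantile normalisation, centring of each array on its median, all probe sets in place of 1 per gene, leaving out probe sets with the suffixes _x_at, _s_at and _a_at, no variance trend, only the arrays of the groups compared, array weights, the replicate number as a block, an adjusted p under 0.01, limma treat against a 1.2-fold change, camera with an estimated correlation, limma fry, and leaving out each array in turn. Their effect is given with the closing observations.

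The fit was tested on simulated data built on the spread of these arrays. For the wild-type response, 11 of 11004 unchanged genes were called among 11184 genes. Of the genes given a log2 change, 62.1% were recovered at 0.5, 83.6% at 1 and 88.1% at 2. For the interaction, 9 of 11006 unchanged genes were called among 11190 genes, with 51.5%, 67.2% and 94.0% recovered at those sizes. Of 30 simulated lists of 20 genes in the wild-type contrast, all 5 that were shifted by 0.3 were called by camera, and 0 others. The simulated noise was independent between genes, whereas the correlation estimated for the real proteasome list in that contrast was 0.354. Only 66 or 67 genes were changed at each size, whereas 63.96% of tested genes were called in the real wild-type response. The simulated rates of false calls therefore do not carry over to the real lists and counts. Array data carry no counts, so the number of arrays and the signal over background limit the precision. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6. Probe sets without a gene name, or with several, were left out of the gene tests, since their values cannot be assigned to 1 gene.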

Results

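RNA of wild-type and CHOP knockout mouse embryonic fibroblasts was measured on 16 arrays, 4 for each combination of genotype and treatment. CHOP, the product of Ddit3, is a transcription factor induced by the integrated stress response, and MG132 blocks the proteasome, so that misfolded and short-lived proteins accumulate. The title of the series states the aim of finding genes whose response to proteasome inhibition depends on CHOP. The median signal per array averaged 97.7 in untreated and 101.9 in treated wild-type cells, and 97.52 and 94.2 in the knockout cells. Arrays of a group correlated with each other at 0.985 to 0.992 across genes. The 3' to 5' ratio of Gapdh averaged 0.849 and 0.845 in the wild-type groups and 0.830 and 0.823 in the knockout groups. That of Actb averaged 1.16 without and 1.23 with MG132 in wild-type cells, and 1.15 and 1.21 in knockout cells (exact permutation p = 0.0286 in each genotype, BH adjusted 0.137). The upper quartile of the signals was lower with MG132, 829.7 against 892.6 in wild-type and 796.8 against 867.6 in knockout cells (exact permutation p = 0.0286 in each, BH adjusted 0.137), and the treated knockout cells lay below the treated wild-type cells at the same p. Centring the arrays on their medians moved the median of all genes by 0.20 in the wild-type and 0.14 in the knockout response. Medians of the lists described that change sign with it are named. Single genes with falls smaller than this shift turn as well, and not all of them are named.

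Ddit3 itself rose with MG132 in wild-type cells and did not pass the test in knockout cells. Its probe set 1417516_at gave 1017 ± 101 in untreated and 7724 ± 587 in treated wild-type cells, a log2 change of 2.91 (SE 0.09). In knockout cells it gave 368 ± 24.0 and 396 ± 38.9, a change of 0.10 (SE 0.09, limma adjusted p = 0.33), which passed the threshold under quantile normalisation (0.25) and median centring (0.24). All 4 treated wild-type arrays lay above all other arrays, and the difference between both responses was -2.81 (SE 0.12). A further probe set of the gene, 1443897_at, stayed at 258 and 286 in wild-type and at 256 and 290 in knockout cells, so that the mean of both probe sets gave 1.54 for the wild-type response and -1.40 for the difference. Where either probe set lies relative to the deleted part of the gene is not given in the sources used here. Atf5, a stress-induced transcription factor related to ATF4 and described as a target of CHOP, was measured by 1 probe set, 1425927_a_at. It fell in wild-type cells from 2516 ± 548 to 1364 ± 175, a change of -0.86 (SE 0.12, limma adjusted p = 2.7e-06). In knockout cells it gave 703 ± 51.5 and 740 ± 44.4, a change of 0.07 (SE 0.12, adjusted p = 0.62), and the responses differed by 0.93 (SE 0.17, adjusted p = 0.00036).

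**Figure D1:**
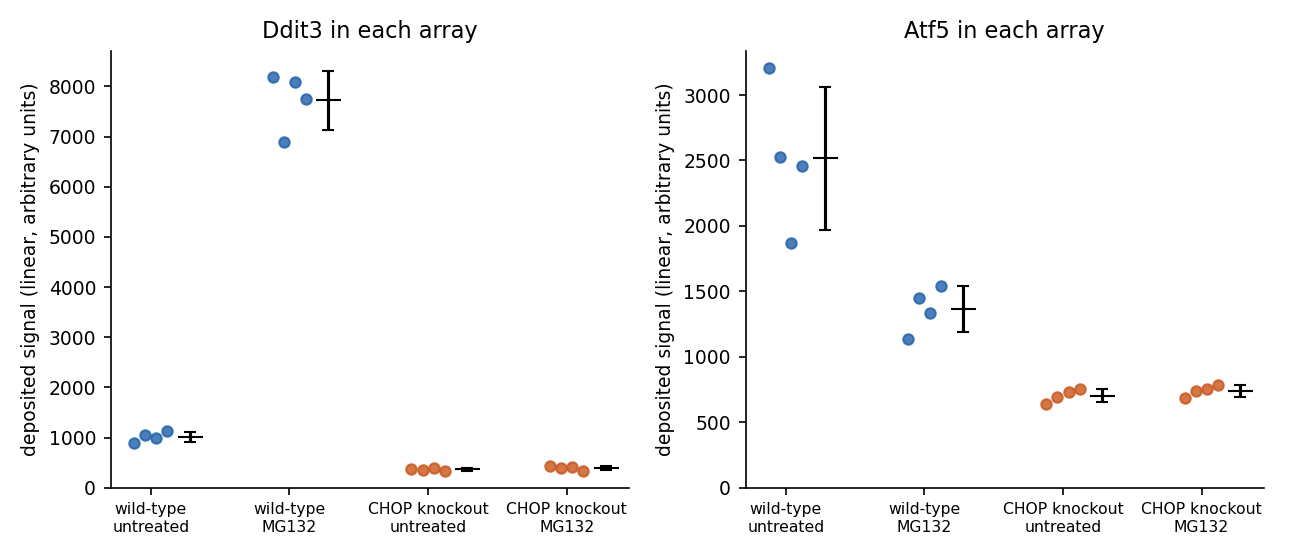
Linear MAS5 signal of Ddit3 and Atf5 on each of the 16 arrays by group, with black bars for the mean ± SD of 4 arrays. Ddit3 reached 7724 in treated wild-type cells and stayed at 368 and 396 in knockout cells, and Atf5 was highest in untreated wild-type cells at 2516.

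The response of wild-type cells shows what proteasome inhibition changed where CHOP was present. The cells raised genes of protein folding and stress signalling. Hspa1a, an inducible HSP70 chaperone, rose from a signal of 1208 to 36336, a log2 change of 4.89 (SE 0.07). Atf3, a stress-induced transcription factor, rose by 4.36 (SE 0.06) from 468 to 9921, and Pmaip1, which encodes the pro-apoptotic protein NOXA, by 4.25 (SE 0.07) from 978 to 18916. Serpinb9g, a member of the serpin family of protease inhibitors, rose by 8.29 (SE 0.16), from a background signal of 6.53 to 6975. The growth-induced transcription factor Egr1 fell from 18863 to 602, a change of -4.93 (SE 0.09).

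Other leading rises were those of the collagenase Mmp13 at 5.74 (SE 0.28), Dynap at 4.94 (SE 0.19), the keratins Krt16 at 4.76 (SE 0.27) and Krt14 at 4.22 (SE 0.33), the protease granzyme B (Gzmb) at 4.39 (SE 0.40), and the carbonic anhydrase Car6 at 3.86 (SE 0.31). Several genes started near the background, Serpinb9g at 6.53, Mmp13 at 21.3, Gzmb at 22.8 and Krt14 at 10.1, so the size and rank of their change depend on the constant added to the signals. With pseudocounts of 1 and 64 Serpinb9g gave 10.05 and 6.64, and Gzmb 5.71 and 3.07. Among the falls were Egr3 at -4.44 (SE 0.17) and Egr2 at -3.15 (SE 0.26), of the same family as Egr1, although the average over all probe sets of Egr3 gave -1.68 and that of Ripor2 -1.65. Smad6, an inhibitor of BMP signalling, fell, at -2.49 (SE 0.10). Other falls were those of Atoh8 at -3.16 (SE 0.33), Angptl7 at -2.77 (SE 0.25), Klhdc8a at -2.65 (SE 0.09), the sulfotransferase gene Chst12 at -2.53 (SE 0.19) and Ripor2 at -2.49 (SE 0.10). For each of these genes the 4 treated arrays lay on one side of the 4 untreated ones.

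By list, 29 of 32 targets of the ISR and ATF4 rose and 2 fell, with a median of 1.00 (camera adjusted p = 3.45e-15, adjusted p = 0.00863 with an estimated correlation). Among the rises were Atf3, Chac1, which degrades glutathione, at 3.68, the cystine transporter gene Slc7a11 at 3.81 and the pseudokinase gene Trib3 at 2.29. The members that fell were Atf5 and the serine synthesis gene Psat1 (-0.18), the latter named after its values were seen. Under median centring 30 members rose and only Atf5 fell, as the shift of 0.20 exceeds the fall of Psat1 and turns its direction. Of 19 aminoacyl-tRNA synthetases, which charge tRNAs, 15 rose and 1 fell, with a median of 0.47 (camera adjusted p = 3.09e-06, adjusted p = 0.0165 with an estimated correlation), Cars by 1.37, Wars by 1.14, Tars by 0.93 and Rars by 0.79. Heat shock proteins and cytosolic chaperones rose in 22 of 24 members, 23 when adjusted over the list alone, with a median of 0.92 (camera adjusted p = 3.45e-15, adjusted p = 0.00546 with an estimated correlation). These included the small heat shock proteins Hspb1 at 3.85 and Cryab at 2.31 and the HSP110 chaperone Hsph1 at 1.96.

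Of 36 subunits of the 26S proteasome, 31 rose and 1 fell, with 32 and 1 adjusted over the list alone and a median of 0.42, among them Psmb2 at 0.84, Psmd1 at 0.65, Psmd14 at 0.61 and Psmc6 at 0.59. The camera adjusted p was 5.77e-10, but adjusted p = 0.161 with an estimated correlation. In the ubiquitin and p97 pathway 11 of 13 members rose and 1 fell, with a median of 0.44 (camera adjusted p = 3.3e-05, adjusted p = 0.00727 with an estimated correlation), with Zfand2a, which associates with the proteasome under stress, at 2.67, and the p97 cofactors Nploc4 at 0.95 and Ufd1 at 0.92. Of 17 autophagy genes 10 rose and 4 fell, with a median of 0.22 (camera adjusted p = 0.00762, but adjusted p = 0.107 with an estimated correlation), including the autophagy receptors Sqstm1 (p62) at 2.06 and Nbr1 at 0.59. Of 15 NRF2 antioxidant genes 12 rose and 1 fell, with a median of 0.73 (camera adjusted p = 3.09e-06, but adjusted p = 0.107 with an estimated correlation), including heme oxygenase (Hmox1) at 2.80, Osgin1 at 2.45 and sulfiredoxin (Srxn1) at 1.78.

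Of 14 NF-kB and cytokine genes 7 rose and 4 fell, with a median of 0.65 (camera adjusted p = 0.0276, but adjusted p = 0.163 with an estimated correlation), and the call was lost when only the groups compared were fitted. The chemokines Ccl2, Cxcl10 and Ccl7 rose by 3.52, 3.04 and 2.79, and the NF-kB subunit gene Relb by 2.66. Of 20 genes of cholesterol synthesis and uptake 15 rose and 4 fell, with a median of 0.46 (camera adjusted p = 0.000173, but adjusted p = 0.132 with an estimated correlation), with the sterol synthesis enzymes Cyp51 at 1.33 and Sc5d at 0.85. Mitotic genes fell in 18 of 27 members and rose in 4, with a median of -0.33, or 13 and 7 with a median of -0.13 under median centring (camera adjusted p = 0.00253, but adjusted p = 0.107 with an estimated correlation). Among them were the mitotic kinase Aurkb at -1.28, the kinesin Kif2c at -0.94, Birc5, which encodes survivin, at -0.89, and cyclin B2 (Ccnb2) at -0.82. Of 23 cytosolic ribosomal proteins 16 rose and 3 fell, with a median of 0.19 (camera adjusted p = 0.0418, but adjusted p = 0.664 with an estimated correlation). Rps19 rose by 0.30 and Rpl37 changed by -0.48. The call was lost under quantile normalisation (median 0.01) and other settings, and without replicate 1 or 4 of untreated (medians 0.12 and 0.17) or replicate 1, 3 or 4 of treated wild-type cells (0.18, 0.15 and 0.18).

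The other lists did not pass camera in wild-type cells. Of 23 ER chaperones and ERAD genes 10 rose and 6 fell (median 0.11, camera adjusted p = 0.054), but 15 rose and 1 fell under median centring (median 0.32), with the ER co-chaperone gene Dnajb9 at 1.59 and Herpud1, an ERAD component, at 1.15. In the immunoproteasome and antigen processing list 4 of 8 rose and 2 fell (median 0.41, adjusted p = 0.0876), with the MHC class I genes H2-K1 at 1.27 and B2m at 0.59. Apoptosis regulators rose in 10 and fell in 10 of 22 members (median 0.09, adjusted p = 0.304), with the death receptor gene Tnfrsf10b at 1.81 and Ppp1r15a, which directs dephosphorylation of eIF2 alpha, at 2.14. Of 17 p53 targets 8 rose and 5 fell (median 0.11, adjusted p = 0.054), with Trp53inp1 at 2.14 and Ei24 at -0.99. AP-1 and immediate early genes rose in 7 and fell in 9 of 19 members, with a median of -0.14 that became 0.06 under median centring (adjusted p = 0.555), Ier2 at -1.25 and Ier3 at 1.54. Interferon response genes rose in 5 and fell in 1 of 12 (median 0.40, adjusted p = 0.252), with Ifit1 at 1.46 and Ifit2 at -0.97. DNA replication genes rose in 9 and fell in 9 of 30, or 9 and 8 adjusted over the list alone, but in 20 and 4 under median centring. Their median of 0.02 and the direction of camera were positive while their mean was -0.06 (adjusted p = 0.518), the median became -0.08 under quantile normalisation and 0.22 under median centring, and thymidine kinase (Tk1) changed by -2.01.

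Extracellular matrix genes rose in 9 and fell in 16 of 28 (median -0.22, adjusted p = 0.317), but in 11 and 11 under median centring (median -0.02), with the collagen gene Col3a1 at -1.36 and the protease inhibitor Timp3 at 1.74. Contractile and serum response genes rose in 2 and fell in 10 of 16, or 4 and 10 adjusted over the list alone (median -0.41, adjusted p = 0.054), and 6 and 8 under median centring (median -0.20), with the myosin light chain gene Myl9 at -1.92 and the calponin Cnn2 at -1.79. Fibroblast identity genes rose in 3 and fell in 8 of 14 (median -0.42, adjusted p = 0.305), and 4 and 6 under median centring (median -0.22), with Prrx2 at -1.44 and the PDGF receptor gene Pdgfrb at -1.43. Hox genes rose in 2 and fell in 6 of 19, with a median of -0.20 that became 0.01 under median centring (adjusted p = 0.646). Oxidative phosphorylation genes rose in 4 and fell in 15 of 28, with a median of -0.14 that became 0.07 under median centring, with 13 and 5 (adjusted p = 0.252), and the complex II subunits Sdhc and Sdhd changed by -0.99 and -0.73. Of 4 sex-linked transcripts 2 rose and 1 fell, with a median of 0.16 and a positive camera direction but a mean of -0.01 (adjusted p = 0.597).

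Markers of other cell types changed in single genes, and none of their lists passed. Epithelial markers rose in 4 and fell in 1 of 7 (median 0.26, adjusted p = 0.184), with Krt14 and Sfn (1.62) rising and Krt7 at -1.06. Macrophage and leukocyte markers rose in 3 and fell in 1 of 5 (median 0.47, adjusted p = 0.555), with Cd68 at 0.63. Skeletal muscle markers rose in 1 and fell in 1 of 5 (median 0.20, adjusted p = 0.706), with the troponin gene Tnnt2 at 2.99 and the actin gene Acta1 at -1.11. Of 4 fat cell markers only Cebpa rose, by 1.33 (list median 0.15, adjusted p = 0.555), and of 3 cartilage and bone markers only Sox9, by 2.58 (list median 0.39, adjusted p = 0.327). Neural markers rose in 3 and fell in 2 of 9 (median 0.09, adjusted p = 0.597), with Tubb3 at 1.65 and Nes at -1.24. The endothelial and the placental and red blood cell lists had 2 tested members each and no list test. Eng changed by -0.50 (adjusted p = 0.0058), which did not pass under median centring (-0.30), and Kdr by 0.04, and Afp rose by 3.64 (SE 0.19) while Eomes, at 0.67, did not pass.

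Across all 11457 genes, limma called 3107 higher and 4221 lower with MG132 in wild-type cells, of which 464 and 727 changed at least 2-fold (783 and 416 under median centring). Of the calls 42.4% were higher, against 61.7% (4587 higher, 2853 lower) under median centring, so that the balance of directions depends on the scaling.

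Knockout cells show the response without CHOP. Stress genes rose here too: Hspa1a rose by 5.06 (SE 0.07), Hmox1 by 3.72 (SE 0.05), Atf3 by 3.61 (SE 0.06) and Pmaip1 by 3.79 (SE 0.07). Gadd45a, a growth arrest gene induced by stress, rose by 3.88 (SE 0.07), and Fgf21, a hormone gene induced through ATF4, by 3.16 (SE 0.26). The host genes of small nucleolar RNAs Snhg16 and Snhg12 rose by 3.97 (SE 0.08) and 3.18 (SE 0.04), although the average over all probe sets of Snhg16 gave 2.05. Egr1 and Egr3 fell, at -3.57 (SE 0.09) and -3.48 (SE 0.17).

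Serpinb9g rose by 4.55 (SE 0.16) and the tubulin gene Tubb3 by 3.31 (SE 0.18). Falls included the growth arrest gene Gas1 at -2.87 (SE 0.13), the inhibin subunit gene Inhbb at -2.80 (SE 0.26), the matrix protease gene Adamts5 at -2.77 (SE 0.09), Klhdc8a at -2.69 (SE 0.09), Smim27 at -2.51 (SE 0.39), Arsj at -2.50 (SE 0.15), Haghl at -2.48 (SE 0.09) and Hivep3 at -2.46 (SE 0.12). Each of these 20 genes had its 4 treated arrays on one side of the 4 untreated ones. Smim27 gave -3.89 with a pseudocount of 1 and -1.33 with one of 64. Haghl lost its call without suffixed probe sets (-0.47), and averages over all probe sets gave -0.95 for Hivep3, -1.46 for Haghl, -1.78 for Egr3 and -1.87 for Gas1.

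Of the 32 ISR and ATF4 targets 31 rose and 0 fell, with a median of 1.03 (camera adjusted p = 4.53e-20, adjusted p = 0.00268 with an estimated correlation), with Chac1 at 2.77, the stress protein gene Nupr1 at 1.77 and the cysteine synthesis gene Cth at 1.61. Aminoacyl-tRNA synthetases rose in 15 and fell in 0 of 19 (median 0.57, camera adjusted p = 2.21e-07, adjusted p = 0.00645 with an estimated correlation), with Cars at 1.32 and Sars at 0.94. Heat shock genes rose in 22 of 24 (median 0.89, camera adjusted p = 2.28e-15, adjusted p = 0.00268 with an estimated correlation), with Hspb1 at 2.65 and the HSP40 co-chaperone Dnajb1 at 1.73. ER chaperones and ERAD genes rose in 15 and fell in 2 of 23 (median 0.34, camera adjusted p = 3.71e-05, adjusted p = 0.00318 with an estimated correlation), with Herpud1 at 1.82, Dnajb9 at 1.74, the ER stress transcription factor gene Xbp1 at 1.10 and Manf at 0.55. Proteasome subunits rose in 32 and fell in 1 of 36 (median 0.33, camera adjusted p = 3.3e-09, but adjusted p = 0.187 with an estimated correlation), with Psmd4 at 0.71 and Psmd1 at 0.63.

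The ubiquitin and p97 pathway rose in 11 of 13 members (median 0.42, camera adjusted p = 1.96e-06, adjusted p = 0.00268 with an estimated correlation), with Zfand2a at 2.38 and Zfand5 at 1.15. Autophagy genes rose in 9 and fell in 3 of 17 (median 0.20, camera adjusted p = 0.00379, but adjusted p = 0.0984 with an estimated correlation), with Sqstm1 at 2.09 and Gabarapl1 at 1.39, and lost the call without suffixed probe sets. NRF2 genes rose in 13 and fell in 1 of 15 (median 0.75, camera adjusted p = 2.71e-07, but adjusted p = 0.0644 with an estimated correlation), with Osgin1 at 2.60 and Srxn1 at 1.97. Cholesterol genes rose in 14 and fell in 3 of 20 (median 0.46, camera adjusted p = 0.000184, but adjusted p = 0.164 with an estimated correlation), with Cyp51 at 1.21 and Insig1 at 1.15. Extracellular matrix genes fell in 17 and rose in 4 of 28, or 18 and 4 adjusted over the list alone (median -0.53, camera adjusted p = 0.00309, but adjusted p = 0.223 with an estimated correlation), with Col3a1 at -2.19 and the thrombospondin Thbs1 at -1.66. NF-kB and cytokine genes rose in 9 and fell in 4 of 14 and did not pass (median 0.65, adjusted p = 0.0502), nor did mitotic genes, with 7 rising and 12 falling of 27 and a median of -0.07 that became 0.07 under median centring (adjusted p = 0.418). AP-1 genes rose in 8 and fell in 7 of 19, with a median of 0.03, a positive camera direction and a mean of -0.16 (adjusted p = 0.265).

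In knockout cells limma called 2942 genes higher and 4205 lower, 345 and 638 of them by at least 2-fold (403 lower under median centring). The share of higher calls was 41.2%, against 55.8% (3993 higher, 3167 lower) under median centring.

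The difference between both responses was tested directly, and compares the cells of both genotypes rather than CHOP alone. The genes whose rise was weaker in the knockout included Mmp13, which rose by 5.74 in wild-type cells and changed by -0.45 in knockout cells (not past the threshold), a difference of -6.19 (SE 0.40). Dynap rose by 4.94 against 0.49 (difference -4.45, SE 0.26), Serpinb9g by 8.29 against 4.55 (-3.74, SE 0.23) and Krt16 by 4.76 against 1.22 (-3.53, SE 0.39). Corneodesmosin (Cdsn), a protein of the cornified layer of skin, rose by 2.90 in wild-type cells and changed by -0.51 in knockout cells (-3.41, SE 0.25). In the other direction Fam13c changed by -1.50 in wild-type and 1.80 in knockout cells (3.30, SE 0.21), and the lipoprotein receptor gene Vldlr by 0.08 (not past the threshold) and 1.95 (1.87, SE 0.13).

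Further genes with a lower response in the knockout were the keratin-associated protein gene Krtap1-5 (-3.37, SE 0.39), Car6 (-3.30, SE 0.43), the growth factor gene Igf1 (-3.23, SE 0.51), the placental prolactin family gene Prl8a9 (-3.03, SE 0.61) and the keratin gene Krt25 (-2.93, SE 0.53). Genes with a higher response in the knockout were Lrrtm3 (2.56, SE 0.35), the transcription factor gene Bcl11b (2.42, SE 0.54), Angptl7 (2.38, SE 0.36), Egr2 (2.32, SE 0.37), Clba1 (2.30, SE 0.13), the connexin gene Gjb5 (2.18, SE 0.57), Carns1 (2.11, SE 0.40) and the VEGF receptor gene Kdr (1.82, SE 0.60, limma adjusted p = 0.027). Bcl11b gave 1.09 without suffixed probe sets, Prl8a9 ranged from -4.59 to -1.71 with pseudocounts of 1 and 64, and Gjb5 lost its call with a pseudocount of 1 (2.98). With a pseudocount of 64 Gjb5 gave 1.32 and Kdr 1.13. Kdr lost its call without replicate 3 of untreated knockout (1.45), of treated wild-type (1.37) or of treated knockout cells (1.62).

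**Figure D2:**
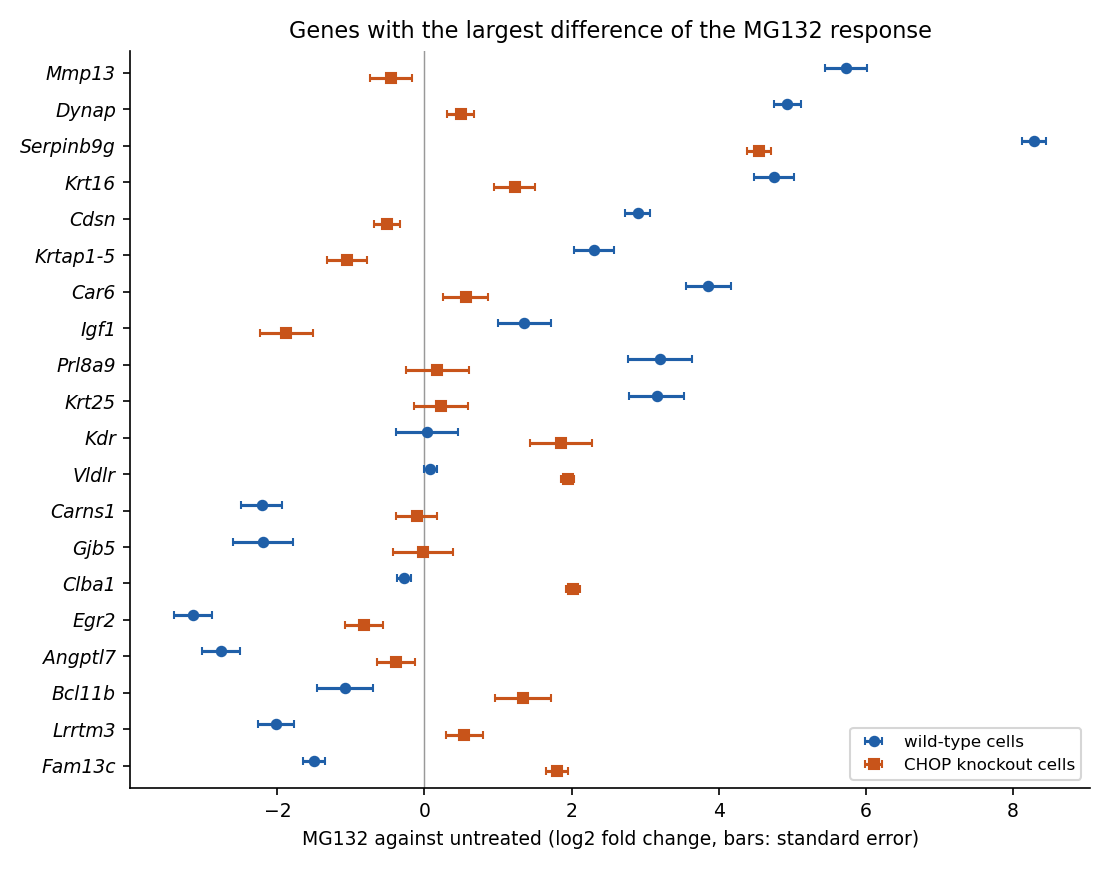
Log2 fold change (MG132 against untreated) ± SE of the 20 genes with the largest differences between both responses, circles for wild-type and squares for knockout cells, 4 arrays per group. Mmp13 rose by 5.74 in wild-type cells and changed by -0.45 in knockout cells, and Fam13c moved in opposite directions.

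Among the lists, ER chaperones and ERAD genes responded more in the knockout in 7 of 23 members and less in 0, with 8 and 0 adjusted over the list alone (median difference 0.15, camera adjusted p = 0.0046, but adjusted p = 0.0542 with an estimated correlation). Xbp1 differed by 1.17, Herpud1 by 0.68 and Manf by 0.52, but Xbp1 lost its call without suffixed probe sets (0.54). AP-1 and immediate early genes were higher in 11 and lower in 2 of 19 (median 0.54, camera adjusted p = 4.49e-05, but adjusted p = 0.147 with an estimated correlation), with Egr1 at 1.35, Ier2 at 1.05 and Fosl2 at 0.87. Mitotic genes were higher in 13 and lower in 0 of 27 (median 0.19, camera adjusted p = 1.49e-05, but adjusted p = 0.0542 with an estimated correlation), with Birc5 at 0.59 and the kinase Bub1b at 0.55. Contractile genes were higher in 8 and lower in 1 of 16 (median 0.24, camera adjusted p = 0.000282, but adjusted p = 0.264 with an estimated correlation), with the actin-binding protein gene Tagln at 1.03 and Cnn2 at 0.91. NF-kB and cytokine genes were lower in 8 and higher in 3 of 14, with 9 and 3 adjusted over the list alone (median -0.58, camera adjusted p = 0.0159, but adjusted p = 0.201 with an estimated correlation). Ccl2 differed by -1.76 and the NF-kB inhibitor gene Tnfaip3 by -1.37, and the list lost its call without suffixed probe sets. Extracellular matrix genes were lower in 14 and higher in 1 of 28 (median -0.31, camera adjusted p = 3.94e-05, but adjusted p = 0.151 with an estimated correlation), with Thbs2 at -0.96 and the collagen gene Col6a3 at -0.91.

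The ISR list as a whole did not pass: 10 of 32 members were higher and 8 lower in the knockout response, or 11 and 8 adjusted over the list alone. Its median of 0.03 became -0.01 under quantile normalisation and -0.03 under median centring (camera adjusted p = 0.603). Within it Vldlr, Ddit4, an inhibitor of mTOR signalling (0.82), and Cth (0.64) were higher, and Atf3 (-0.76) was lower. Heat shock genes were higher in 2 and lower in 5 of 24 (median -0.08, adjusted p = 0.245), with Hspb1 at -1.20 and Hspb8 at -0.81. Of 22 apoptosis regulators 3 were higher and 6 lower, or 4 and 6 adjusted over the list alone, and their median of -0.04 became 0.01 under quantile normalisation (adjusted p = 0.738). Tnfrsf10b differed by -1.17 and Bcl2l11, which encodes the pro-apoptotic protein BIM, by -1.06. Of 17 p53 targets 5 were lower and 0 higher (median -0.16, adjusted p = 0.0527), with Trp53inp1 at -1.43 and Pmaip1 at -0.46. Epithelial markers were lower in 3 of 7 (median -0.32, adjusted p = 0.245), with Krt14 at -2.66 and Sfn at -2.06.

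**Figure D3:**
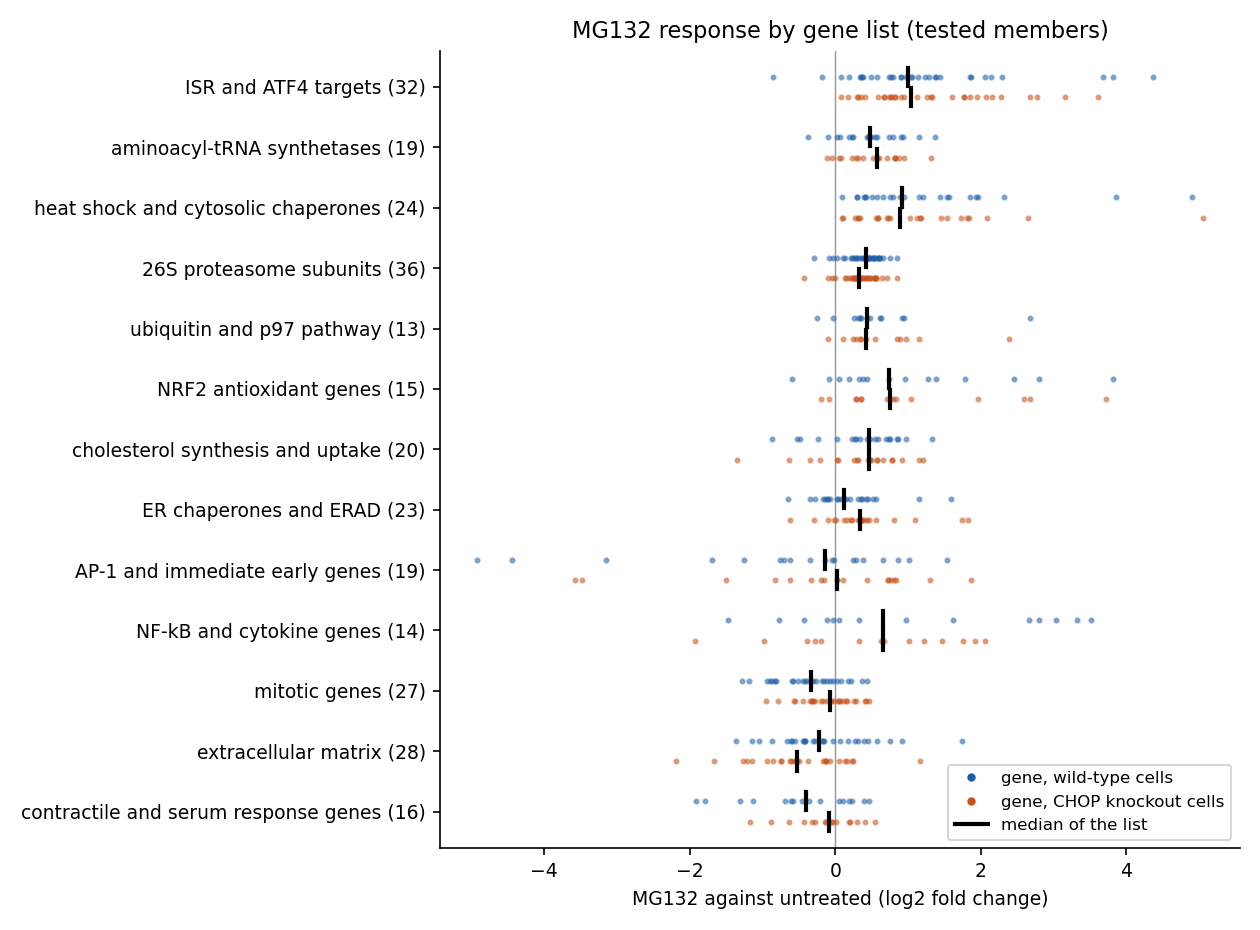
Log2 fold change of the members (dots) and the median (black bar) of 13 gene lists in wild-type and knockout cells, MG132 against untreated, from 4 arrays per group. The ISR medians were 1.00 and 1.03, while the medians of AP-1 genes in wild-type and of mitotic and contractile genes in knockout cells change sign under median centring.

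For the difference between both responses limma called 1620 genes higher and 1615 lower in the knockout, 119 and 260 of them by at least 2-fold. Higher calls made up 50.1%, against 38.3% (1252 higher, 2015 lower) under median centring. Of the genes of the wild-type response, 2556 also passed the test of the difference. In 878 a rise was weaker in the knockout, of which 359 still rose there, 370 did not pass and 149 fell. In 248 the rise was stronger, in 1097 a fall was weaker (495 still fell, 433 did not pass, 169 rose) and in 333 a fall was stronger. Under median centring weaker rises numbered 1346 and weaker falls 682, so that their balance turned. Of the 464 genes that rose at least 2-fold in wild-type cells, 133 had a response at least 2-fold weaker in the knockout. Of the 727 that fell as much, 66 did. The wild-type arrays enter both tests with opposite signs, so genes picked by their wild-type response tend to appear weaker in the knockout. The excess of weaker over stronger responses is therefore partly built in. No count was made that starts from the knockout response.

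Both responses were alike across genes, with a Pearson correlation of 0.733 and a Spearman correlation of 0.726 over 11457 genes, which are not independent replicates. 2145 genes rose in both genotypes where independent lists would share 797.8, and 3177 fell in both where these would share 1549. Only 149 rose in wild-type and fell in knockout cells, and 169 did the reverse. The genes that rose at least 2-fold in wild-type cells had a median change of 1.39 there and 0.89 in the knockout, and those chosen in the knockout had 1.27 there and 1.12 in wild-type cells.

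**Figure D4:**
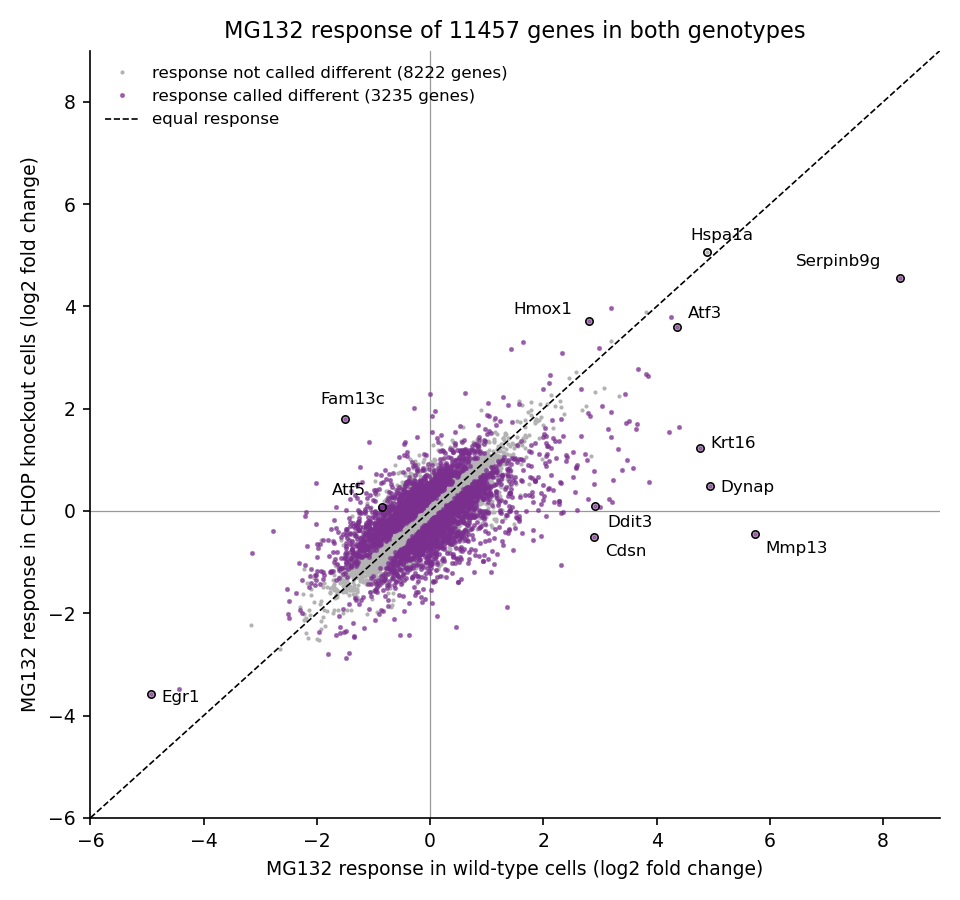
Log2 fold change with MG132 of 11457 genes in wild-type cells (horizontal axis) against knockout cells (vertical axis), each from 4 treated and 4 untreated arrays. The 3235 genes with a called difference between the responses are purple, all others grey, and the dashed line marks equal responses.

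The untreated cells of both genotypes already differed widely. In knockout cells Sprr1a, a protein of the cornified envelope, was 7.55 (SE 0.28) higher, at 11699 against 54.7. The retinoic acid binding protein gene Crabp1 was 6.54 (SE 0.13) higher, at 16455 against 164, and Cd34, a surface glycoprotein of progenitor cells, 5.10 (SE 0.08) higher, at 9357 against 260. Coch, a secreted matrix protein, was lower by -7.63 (SE 0.11), at 89.3 against 20819, and the transcription factor gene Mycn by -7.56 (SE 0.21), at 158 against 31944. The Y-linked translation factor gene Eif2s3y was at 11.1 in knockout against 4714 in wild-type cells (-7.54, SE 0.21), and Xist, the RNA that silences an X chromosome in female cells, was higher by 5.05 (SE 0.11).

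The growth factor gene Ptn was higher by 6.31 (SE 0.12), Ankrd1 by 6.09 (SE 0.11), the amino acid transporter gene Slc38a1 by 6.002 (SE 0.09), Bex1 by 5.52 (SE 0.15), the coagulation inhibitor gene Tfpi by 5.47 (SE 0.17), the imprinted gene Ndn by 5.09 (SE 0.10) and Rps6ka6 by 5.07 (SE 0.27). The cysteine dioxygenase gene Cdo1 was lower by -6.84 (SE 0.16), Angptl7 by -6.40 (SE 0.25), the sulfatase gene Sulf1 by -6.33 (SE 0.19), Stmn2 by -6.19 (SE 0.18), Syt7 by -6.04 (SE 0.30), Tnfrsf11b, which encodes osteoprotegerin, by -5.69 (SE 0.19) and Tfap2b by -5.48 (SE 0.33). For each gene named here for untreated cells all 4 knockout arrays lay on one side of the 4 wild-type ones. The average over all probe sets was -2.81 for Mycn, and Slc38a1 gave 4.003 without suffixed probe sets.

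ISR and ATF4 targets were higher in 20 and lower in 5 of 32 (median 0.31, camera adjusted p = 0.00384, but adjusted p = 0.354 with an estimated correlation), with Cth at 2.27 and Vldlr at -3.49. Fibroblast identity genes were lower in 10 and higher in 2 of 14 (median -0.67, camera adjusted p = 0.00393, but adjusted p = 0.172 with an estimated correlation), with the PDGF receptor gene Pdgfra at -4.19 and the surface marker Thy1 at 3.497. AP-1 genes were lower in 12 and higher in 2 of 19 (median -0.32, camera adjusted p = 0.00384, but adjusted p = 0.354 with an estimated correlation), with Klf4 at -2.41 and Junb at -1.40. NF-kB and cytokine genes were higher in 9 and lower in 4 of 14 (median 0.77, camera adjusted p = 0.0245, but adjusted p = 0.354 with an estimated correlation), with Ccl2 at 2.93 and Cxcl5 at -2.34, and lost the call when only the groups compared were fitted. Proteasome subunits were higher in 23 and lower in 1 of 36, or 23 and 2 adjusted over the list alone (median 0.16, camera adjusted p = 0.00384, but adjusted p = 0.623 with an estimated correlation), with Psmd7 at 0.49. Oxidative phosphorylation genes were higher in 21 and lower in 2 of 28 (median 0.20, camera adjusted p = 0.00384, but adjusted p = 0.61 with an estimated correlation), with Cox6c at 0.50. The immunoproteasome list was higher in 6 of 8 (median 0.57, camera adjusted p = 0.0189, but adjusted p = 0.354 with an estimated correlation), with Tapbp at 0.77 and H2-K1 at 0.64, and lost the call without suffixed probe sets.

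Hox genes, which mark position along the body axis and limb, were higher in 9 and lower in 5 of 19, or 10 and 5 adjusted over the list alone. Their median of 0.26 and the camera direction were positive and their mean was -0.32 (adjusted p = 0.906). Those with the smallest adjusted p were all of the Hoxd cluster, with Hoxd10 at -5.47, Hoxd8 at -4.48, Hoxd13 at -4.17 and Hoxd11 at -4.003. Of 4 sex-linked transcripts 1 was higher and 3 were lower (median -3.02, adjusted p = 0.273), with Uty at -3.15 and Kdm5d at -2.89. Limma called 3270 genes higher and 3071 lower in untreated knockout cells, 613 in each direction by at least 2-fold. Higher calls made up 51.6%, against 61.0% (3903 higher, 2491 lower) under median centring.

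Between the treated cells of both genotypes, Ptn was higher in the knockout by 6.73 (SE 0.12), Ankrd1 by 6.21 (SE 0.11), Sprr1a by 6.06 (SE 0.28), Crabp1 by 6.01 (SE 0.13), Slc38a1 by 5.38 (SE 0.09), Cd34 by 5.06 (SE 0.08), Bex1 by 4.89 (SE 0.15), Tfpi by 4.77 (SE 0.17), Xist by 4.61 (SE 0.11) and Pdzrn3 by 4.60 (SE 0.32). Mycn was lower by -7.79 (SE 0.21), Eif2s3y by -7.72 (SE 0.21), Tnfrsf11b by -7.55 (SE 0.19), Coch by -7.19 (SE 0.11), Mmp13 by -6.45 (SE 0.28), Sulf1 by -6.05 (SE 0.19), the thrombomodulin gene Thbd by -5.92 (SE 0.11), Cdo1 by -5.85 (SE 0.16), Syt7 by -5.35 (SE 0.30) and Hoxd10 by -5.27 (SE 0.18). All 4 arrays of one genotype lay on one side of the other 4 for each of them, and averages over all probe sets gave -3.91 for Mycn and 4.26 for Ptn. Ddit3 and Atf5 were lower by -4.23 and -0.86, after -1.43 and -1.79 in untreated cells.

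Fibroblast identity genes were lower in 11 and higher in 2 of 14 (median -0.90, camera adjusted p = 0.000503, adjusted p = 0.0346 with an estimated correlation), with Pdgfra at -4.002 and Prrx2 at -1.94. Markers of other cell types did not pass camera, though epithelial markers were lower in 4 and higher in 0 of 7 (median -1.26, adjusted p = 0.0976) and fat cell markers lower in 3 and higher in 1 of 4 (median -1.25, adjusted p = 0.323). ISR targets were higher in 21 and lower in 7 of 32, or 21 and 8 adjusted over the list alone (median 0.46, camera adjusted p = 0.00411, but adjusted p = 0.497 with an estimated correlation), with Cth at 2.91 and Ddit4 at 2.09. Contractile genes were higher in 11 and lower in 1 of 16 (median 0.43, camera adjusted p = 0.00354, but adjusted p = 0.497 with an estimated correlation), with Cnn1 at 2.09 and Myl9 at 1.46. Limma called 3508 genes higher and 3206 lower, 515 and 700 of them by at least 2-fold. Each genotype was represented by cells that the labels do not divide further, so these differences cannot be assigned to Ddit3 alone, as in the comparison of untreated cells.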

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

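4 tests in this part were chosen only after the result was seen: those of arrays exchanged between the genotypes, of a lack of CHOP against other differences of the cell populations, of epithelial cells, and of a fault of the Atf5 probe set.

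A single array lay far from the other 3 of its group in 18 of 428 groups tested, where chance marks about 1 in 20 (5%). The upper quartile of treated knockout replicate 2 was 812.5. In untreated wild-type cells, replicate 3 had 73.88 for Gzmb, 5092 for Vldlr and a mean log2 signal of 7.271 for macrophage and leukocyte markers, and replicate 4 had 3624 for Hmox1. In untreated knockout cells, replicate 2 had 25.34 for Krt14, 309.7 for Vldlr, 2.058 for Tfap2b and a mean of 11.45 for autophagy genes, and replicate 4 had 18.44 for Hoxd10. In treated wild-type cells, replicate 3 had 16.43 for Kdr and 36520 for Mycn, and replicate 4 had 212.5 for Hivep3, 3151 for Syt7 and a mean of 12.53 for mitotic genes. In treated knockout cells, replicate 2 had 638.2 for Adamts5, replicate 3 had 1319 for Ndn, and replicate 4 had 601.7 for Egr1.

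Differences between the responses of both genotypes, as knockout minus wild-type on the log2 scale, drew attention in 20 named genes. They were positive for Fam13c (3.296), Lrrtm3 (2.562), Bcl11b (2.421), Angptl7 (2.382), Egr2 (2.318), Clba1 (2.299), Gjb5 (2.177), Carns1 (2.108), Vldlr (1.865) and Kdr (1.818). They were negative for Mmp13 (-6.189), Dynap (-4.446), Serpinb9g (-3.744), Krt16 (-3.533), Cdsn (-3.411), Krtap1-5 (-3.367), Car6 (-3.296), Igf1 (-3.234), Prl8a9 (-3.031) and Krt25 (-2.934). Kdr lost its call without replicate 3 of untreated knockout (1.45), treated wild-type (1.37) or treated knockout cells (1.62). The list medians of this difference were 0.1457 for ER chaperones and ERAD, 0.5393 for AP-1 and immediate early genes, -0.575 for NF-kB and cytokine genes, 0.19 for mitotic genes, -0.3108 for extracellular matrix and 0.2419 for contractile and serum response genes. The response was higher in the knockout for 1620 genes and lower for 1615. Probe sets that name no single gene, 3110 of them tested and unused in the comparisons, carried signals as well. With MG132, 665 were higher and 620 lower in wild-type cells, 454 higher and 730 lower in knockout cells, and for the difference between the responses 170 were higher and 305 lower.

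Regrouping the arrays tested whether a chance division would give as many genes. In each comparison of a single pair of groups, 1 of the 35 splits of the 8 arrays, the real one, gave a count as large. The real counts were 7328 for the wild-type response, 7147 for the knockout response, 6341 for the genotypes untreated and 6714 for the genotypes under MG132, and the highest of the other splits gave 2, 1, 4 and 1. For the difference between the responses, 1 of 100 regroupings of the genotype labels within each treatment reached the real count of 3235. For the genes of the wild-type response that also differed, 1 of 100 reached 2556. The highest others were 2008 and 1344, in 1 regrouping that exchanged the genotypes fully under MG132 and mixed them in untreated cells, so a structure of the samples, the genotype difference itself, enters such counts. A division that mixes the groups moves their real difference into the spread within groups, so low counts there are built in. The regroupings therefore cannot tell how many calls chance alone would give, and no conclusion is drawn from them.

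The first pattern weighed was the wide difference between the genotypes before treatment. A difference of sex between the cells, which Xist and Eif2s3y show at the RNA level, stays open as a cause. Of 1223 genes at least 2-fold apart with a known chromosome, 61 (4.99%) lay on X or Y, against 3.18% of those tested. Genes on X or Y were thus a small part of the difference. That share does not tell whether genes on other chromosomes differ with sex, so it cannot decide the question. Arrays exchanged between the genotypes are argued against. At the same treatment, 0 arrays had a Ddit3, Xist or Eif2s3y value inside the other genotype's range, on the probe set used. A further probe set of Ddit3 and one of Eif2s3y, of lower signal, overlapped. A lack of CHOP and other differences of the 2 cell populations cannot be told apart, because the labels distinguish 1 population per genotype. The same limit stands behind the difference between the responses, and 11 Hox genes at least 2-fold apart in untreated cells leave a difference in the origin of the cells open.

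The next pattern was the stronger rise of keratin, serpin and prolactin family genes in wild-type cells. Epithelial cells in the treated wild-type cultures cannot be told apart from a rise within the fibroblasts, because the 6 markers other than Krt14 went both ways, with a median change of 0.194 and an SD of 0.905. Sfn (1.62), Krt8 (0.90) and Krt19 (0.26) rose, Krt7 fell (-1.06), and Krt5 changed by 0.12 (SE 0.31) and Epcam by -0.02 (SE 0.27). The scaling of the arrays moved the difference between the responses of the median gene by -0.06 under median centring and 0.01 under quantile normalisation, far less than the difference of the 5 named genes of the pattern (Serpinb9g, Krt16, Krtap1-5, Prl8a9 and Krt25), the smallest of which was -2.93 for Krt25, which argues against scaling as the whole cause, while the calls that 100% of them kept add nothing for genes chosen by their size. A rise within the fibroblasts that needs CHOP, and a difference of the cell populations, also stay open.

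The last pattern was the fall of Atf5 in wild-type cells, where the other ISR targets mostly rose. The scaling of the arrays is argued against as the whole cause, since the change stayed past the threshold at -0.655 (SE 0.115) under median centring and -0.80 under quantile normalisation, although the bound set beforehand, more than 2 SE below -0.5, was not met. That 1 array was out of line is argued against by changes between -0.992 and -0.734 whichever array was left out. A fault of the probe set cannot be told apart from a fall of the transcript, because 0 further single-gene probe sets of Atf5 exist on the array. A different level of Atf5 between the populations, or an effect of CHOP on it, both stay open as untested biological explanations.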

How the results depend on the processing

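All alternatives were chosen before the data were examined. Of the values of named genes under alternatives other than leaving out an array, 7864 kept their direction and side of the threshold, 63 lost a call, 38 gained one and 11 changed sign. For the lists described, 474 kept their call and 38 lost it. Of the summary counts and correlations 386 stayed within 1.5 times or their spread and 83 moved. The low end of the signals is a limit: many of the genes with the largest changes lie near background in 1 group, so that their fold depends on the pseudocount, and no detection calls were used here. Where no cause is named, the cause was not tested.

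The correlation between both responses (0.733 Pearson, 0.726 Spearman) was 0.709 and 0.715 with a pseudocount of 1, and 0.761 and 0.745 with a pseudocount of 64. Without a filter on low values it was 0.604 and 0.545, and with a filter at the 60th percentile 0.770 and 0.771, as more or fewer genes of low signal entered. The cause was not tested for the pseudocounts.

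Under median centring, the genes at least 2-fold higher and lower numbered 783 and 416 in wild-type cells and 403 were at least 2-fold lower in knockout cells. Weaker rises in the knockout then numbered 1346 and weaker falls 682. These shifts follow from the shift of all genes by the centring.

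With all probe sets, more features were tested, and the counts grew. Higher and lower were 6530 and 7427 in wild-type (1079 and 1298 at least 2-fold), 5637 and 7701 in knockout (683 and 1220), and 2555 and 3097 for the difference between responses (231 and 609). Between genotypes they were 6011 and 5770 untreated (1147 and 1292) and 6173 and 6870 under MG132 (982 and 1624). Weaker rises numbered 1781, weaker falls 1704, and rises of at least 2-fold that were at least 2-fold weaker 294. The correlations were 0.707 and 0.685, and 0.713 (Spearman) without suffixed probe sets.

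Averaging all probe sets of a gene reversed Rps6 in wild-type cells (-0.039) and in the difference (0.22), Rps20 in knockout cells (-0.53), Msmo1 in untreated cells between genotypes (-0.15) and Usp14 under MG132 (-0.032). Leaving out suffixed probe sets reversed Rps20 (-1.20 in knockout cells), Xist (0.35 in knockout cells, 0.25 in the difference), Afp (0.29 in the difference), and, between untreated genotypes, Psmb1 (-0.14) and Msmo1 (-0.76). Probe sets of 1 gene can measure different transcripts, and the cause was not tested.

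The stricter tests called fewer genes by construction. An adjusted p under 0.01 left 1048 higher and 1025 lower for the difference between responses. Against a 1.2-fold change, treat called 1631 higher and 2548 lower in wild-type, 1417 and 2408 in knockout, 382 and 413 for the difference, 1450 and 1451 between untreated and 1633 and 1711 between treated genotypes.

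Camera with an estimated correlation called 4 lists up and 0 down in wild-type, 5 and 0 in knockout, 0 and 0 for the difference, 0 and 0 between untreated genotypes, and 0 up between treated ones. Fry, which does not compare a list with other genes, called 16 up and 7 down in wild-type, 18 and 6 in knockout, 8 down for the difference, 13 and 12 between untreated and 13 and 10 between treated genotypes. Lists called down in wild-type cells numbered 2 without a filter and with array weights, and 3 with quantile normalisation. In knockout cells they numbered 3 without a filter, 4 with quantile normalisation, and 2 with median centring, all probe sets, no suffixed probe sets, only the groups compared or array weights. Down for the difference were 4 with the 60th percentile filter and 5 with quantile normalisation. Between treated genotypes 6 lists were up without a filter and 2 down with the 60th percentile filter. The cause was not tested.

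Leaving out each array in turn gave correlations of 0.722 to 0.733 (Pearson) and 0.714 to 0.726 (Spearman). Genes higher and lower ranged over 2932 to 3095 and 4063 to 4221 in wild-type, 2779 to 3023 and 4000 to 4294 in knockout, 1465 to 1639 and 1483 to 1675 for the difference, 3051 to 3290 and 2868 to 3068 between untreated and 3294 to 3608 and 3033 to 3283 between treated genotypes. Lists down ranged over 1 to 2 in wild-type, 1 to 3 in knockout and 2 to 5 for the difference, and lists up between treated genotypes over 2 to 4. Of the values of named genes, counted for each comparison and each array left out, 105 lost and 21 gained a call, and 10962, called or not, stayed on the same side of the threshold. Of list calls, counted likewise, 5 were lost and 587 kept.

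The labels give replicate numbers 1 to 4 in each group without saying what they stand for. The deviations of equally numbered arrays correlated at -0.0669 to 0.16 over 24 pairs (mean 0.0459), 5 of them over 0.1, and 8 of 16 arrays correlated best with their own number. Most of these correlations were positive, and a block on the number called more genes in each contrast. A weak effect shared by equal numbers therefore stays open. The main fit did not use the numbers, and the block was an alternative. With the replicate block, 3174 genes were higher and 4271 lower in wild-type, 3031 and 4289 in knockout, 1755 and 1729 for the difference, 3346 and 3152 between untreated and 3605 and 3271 between treated genotypes. The block ended the calls of Krt8 in knockout cells and of Col9a1 between treated genotypes, gave calls to Lpl in knockout cells and to Rpl37 and Kdm5d in the difference, and changed no other call of a list or named gene.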

Other observations

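Of the tests in this part, none was chosen after its result was seen, but the gene lists of the next paragraphs were chosen after values of their members had been seen, so their counts describe the data and are not independent tests. Genes named from them were likewise chosen after their values were seen.

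Of 15 keratins and cornified envelope genes, which build the outer layers of skin, 12 rose and 0 fell in wild-type cells (median 0.90), while 4 rose and 5 fell in knockout cells (median 0.07), and 10 differed downward between the responses (median -1.16). B-clade serpins, which inhibit proteases inside cells, rose in 8 of 9 in wild-type (median 2.28) and 6 of 9 in knockout cells (median 1.12), with 5 lower in the difference. Serpinb9c changed by 3.66 and 1.71, Serpinb9b by 2.74 and 1.12, and Serpinb1a by 2.28 and 0.14 in wild-type and knockout cells. The 3 tested prolactin family genes rose in wild-type cells, Prl7c1 by 3.48, Prl8a9 by 3.20 and Prl6a1 by 2.17, and all 3 were lower in the difference (median -2.49). The filter admits genes high on only 4 arrays, so genes high only in treated wild-type cells can enter. Prl7c1 averaged 481 there, and 32.8, 36.3 and 84.2 in untreated wild-type, untreated knockout and treated knockout cells. Tested were 3 of 18 listed prolactin, 9 of 16 serpin and 15 of 25 keratin and cornified envelope genes. The filter therefore partly set these directions. Chemokines rose in 8 and fell in 3 of 14 in wild-type cells (median 2.02), with Ccl5 at 3.31, Cxcl2 at 2.89, Ccl20 at 2.78 and Ccl9 at 2.59, and rose in 6 and fell in 3 in knockout cells (median 0.43), with 9 lower and 2 higher in the difference. Matrix metalloproteinases did not move together: 3 of 8 rose, Mmp13 among them, and 3 fell in wild-type cells, with a median of -0.11 that became 0.09 under median centring.

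Targets of BMP and SMAD signalling fell in 9 and rose in 4 of 15 in wild-type cells (median -0.81) and fell in 8 and rose in 3 in knockout cells (median -0.44), with medians of -0.61 and -0.29 under median centring. The Id genes, inhibitors of differentiation, were among them, with Id1 at -1.34 and -2.44, Id2 at -1.25 and -1.83 and Id3 at -0.96 and -1.53 in wild-type and knockout cells. In untreated cells 13 of these 15 genes were lower in the knockout and 0 higher (median -1.47). Feedback genes of ERK signalling fell in 7 and rose in 2 of 12 in wild-type (median -0.59) and fell in 9 and rose in 2 in knockout cells (median -0.97), with medians of -0.39 and -0.83 under median centring. The phosphatase gene Dusp6 changed by -0.38 and -2.42 (difference -2.04), Spry2 by -1.22 and -1.73, and Dusp4 by 2.36 and 1.90. YAP targets fell in 9 and rose in 2 of 11 in wild-type (median -0.58) and fell in 7 and rose in 2 in knockout cells (median -0.26), with smaller medians of -0.38 and -0.12 under median centring. Hypoxia genes went both ways, with 5 rising and 6 falling of 18 in wild-type (median 0.08) and 8 rising and 7 falling in knockout cells, where the median of -0.06 became 0.08 under median centring and 0.00 under quantile normalisation.

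Host genes of small nucleolar RNAs, whose spliced transcripts are mostly degraded during translation, may respond to MG132 as a group. Of 14 tested, 9 rose and 4 fell in wild-type (median 0.97) and 10 rose and 4 fell in knockout cells (median 0.87). In the difference between the responses 8 were higher and 1 was lower in the knockout (median 0.28). Among the rises were Snhg16 at 3.19 and 3.97, Snhg12 at 2.98 and 3.18, Snhg5 at 2.11 and 2.66, and Snhg17 at 2.09 and 2.51. As these 4 had been seen first, the other 10 served as the test, and 50% of them rose in both genotypes, which lies between the bounds set beforehand for a rise of the whole group (75%) and against it (under 50%). Snhg1 rose by 1.19 and 1.21 and Gas5 by 1.24 and 0.95, whereas Snhg18 fell, at -1.38 and -0.59, and Snhg3 fell, at -1.02 and -0.60. Whether the rise is one of the group or of some of its members stays open.

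A further hypothesis was that genes around Ddit3 differ between the genotypes because the targeted chromosome segment came from another mouse strain. Of the 40 tested genes nearest to Ddit3 in gene order, 20 on each side, 42.5% differed in untreated cells, against 55.4% of all placed genes and 35% to 75% in the middle 95% of 10000 random positions (one-sided permutation p = 0.921). A window of 50 genes on each side could not be placed, since Ddit3 lies near the end of its chromosome, and it was narrowed to 20 before any result was seen. The 40 genes showed no excess of differing genes. As shares of up to 75% lay within the middle 95% of random positions, a segment that changed only some of these genes could not be seen. The test therefore does not decide the hypothesis.

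Different starting levels could produce differences between the responses without any effect of CHOP on the response. Among 5588 genes whose untreated levels differed by less than 1.2-fold between genotypes, 1421 (25.4%) still passed the interaction test. Of all tested genes 28.24% passed it. Untreated levels up to 1.2-fold apart can themselves give a small difference between the responses. Over all genes, 795 of the 3235 calls remained in the test against a 1.2-fold change. The share of 25.4% therefore does not decide the question. Starting levels as the whole cause are argued against only for those of the 1421 genes that meet 2 conditions. Their difference exceeded 1.2-fold, and their untreated signals lay above the background. The number of such genes was not counted. Of the 133 genes with a rise of at least 2-fold in wild-type cells and a response at least 2-fold weaker in the knockout, 26 had such matched levels. Counted separately, and with matched genes included, the untreated level was called higher in the knockout for 69 of the 133 and lower for 19. Of all 11457 tested genes, 5588 were matched, 3270 were called higher and 3071 lower. The 133 genes were thus less often matched and more often higher in the untreated knockout than tested genes in general. The untreated knockout level enters the difference between the responses with a minus sign. Choosing genes with a weaker response in the knockout therefore favours such levels by construction, and no conclusion is drawn from these shares. For the 133 genes a part of different starting levels stays open. Matched genes included Prg4, a lubricating joint protein (3.59 in wild-type and 0.85 in knockout cells), the decoy receptor genes Tnfrsf23 (3.20 and 1.45) and Tnfrsf22 (3.14 and 1.60), the HSP40 co-chaperone gene Dnaja4 (3.20 and 1.93), Cyp1a1, an enzyme induced by aryl hydrocarbons (2.30 and -0.04), and Tnfrsf10b (1.81 and 0.64). Untreated Prg4 lay near the background, at 27.8 ± 22.3 in wild-type and 32.2 ± 15.3 in knockout cells. Other genes among the 26 did so too, such as Krt14 at 10.1 and 10.4. There the constant added to every signal can make unequal levels appear matched, so equal starting levels are not shown. The matched genes well above the background, such as Tnfrsf23, Tnfrsf22, Dnaja4 and Tnfrsf10b, are candidates for a CHOP-dependent response. Each of these still rose in the knockout. The untreated level of Tnfrsf10b, although within 1.2-fold, was called lower in the knockout, by -0.23 (limma adjusted p = 0.010). The matched genes Cdsn (2.90 and -0.51) and Ccdc71l (1.69 and -0.01) did not rise in the knockout and are candidates too. The limit remains that the labels distinguish 1 population per genotype.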
